A study of Homo sapiens with 4 samples.

How the data were processed

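MicroRNA levels were measured by real-time PCR in 4 human colorectal cancer cell lines, with 1 RNA sample per line. The labels call KM12C and SW480 poorly metastatic and KM12SM and SW620 highly metastatic. The pairing into 2 lineages came from general knowledge of the lines and not from the labels. KM12SM was selected from KM12C through liver metastases in mice, and SW480 and SW620 were derived from a primary tumour and a lymph node metastasis of the same patient. Per the labels' protocols, untreated cells were grown in serum-containing medium, total RNA was isolated with a miRNA kit, reverse transcription used multiplexed primer pools, and products were read on a real-time PCR instrument. The number of PCR wells averaged per value, the Ct threshold and the normalizer were not given in the sources used here.

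The deposited table of raw values held threshold cycles (Ct) for 754 miRNA assays and for the small RNAs RNU44 and RNU48. Ct is the cycle at which a product becomes detectable, so a lower Ct means more RNA and a difference of 1 cycle is about a 2-fold difference. The second deposited table held a relative quantity, a linear ratio with KM12C set to 1 for each assay and rounded to 2 decimals. The third held the authors' linear fold for KM12SM over KM12C and for SW620 over SW480, calculated as a power of the difference of normalized Ct values per the file headers. In the authors' fold table a value of 100 stood where a Ct was obtained for the highly metastatic line alone, and 0 where it was obtained for the poorly metastatic line alone. All 18 assays named after mouse miRNAs lacked a fold in that table and were kept here from their Ct values.

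The authors' normalization was reconstructed from the deposited ratio and Ct values. For each line the log2 ratio plus the Ct difference to KM12C took 1 of 2 constants, which divided the assays into 2 sets, called set A (211 assays) and set B (155 assays). Set membership was inferred from these constants and not from a label, and 387 assays did not have the values to place them. On the log2 scale the constants in set A were -0.55 for KM12SM, -0.39 for SW480 and -0.64 for SW620, and in set B they were -0.71, 0.15 and 0.15. Normalized log2 values were then calculated as the constant minus Ct, which avoids the rounding of low ratios. Ratios rebuilt in this way lay within 0.006 plus 2% of all 295, 318 and 316 deposited ratios of KM12SM, SW480 and SW620. The same tolerance held for all 289 KM12 and 326 SW folds with a Ct in both lines.

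A miRNA was called detected in a line at a Ct under 35, and a fold was calculated where it was detected in both lines of a lineage. Where it was detected in 1 line, a lower bound was calculated against a Ct of 35 in the other, with the constants of the assay's own set. An assay in neither set took the constants that gave the smaller bound. The single miRNA compared without a known set, mmu-miR-499 in SW, took the mean of the constants. All folds are the highly over the poorly metastatic line on the log2 scale, and a miRNA was counted as different at 2-fold or more. With 1 sample per line no replicate check exists within a lineage, and no p-value was calculated there. Each gene list's median fold was set against 10000 random lists of the same size, matched on mean Ct in 10 bins. The percentile describes these samples and is not a test.

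The comparison of highly with poorly metastatic lines over both lineages used limma 3.58.1 in R 4.3.3, with the lineage as a block because the lines of a lineage share an origin. This pairing leaves 1 residual degree of freedom over 230 miRNAs detected in all 4 lines, and eBayes shrank all variances to 1 common value, so each miRNA had the same standard error. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 2 lines of a group are separate cell lines of different patients, so the common variance reflects differences between these lines and not between cultures. It was pooled over all 230 miRNAs, so a p-value on the authors' scale does not measure the spread of its own miRNA. Under the 4 other scalings the prior held 2.10 to 6.73 degrees of freedom, and the variances were not shrunk to 1 value. KM12 and SW origins were compared in the same fit, where the lines of an origin come from 1 patient, so that the number of independent samples is 1 per origin. Fits with 1 line left out had no block and 1 residual degree of freedom, and the lone line of a group was assumed to vary like the other group. Gene lists were tested with limma's camera at a preset correlation of 0.01, and with an estimated correlation as an alternative. On simulated values for the highly against poorly metastatic comparison over 230 miRNAs, limma called 1.25% of 2-fold, 6.25% of 4-fold and 41.5% of 16-fold changes, and 0.44% of unchanged miRNAs. The simulated noise was independent between miRNAs, with a variance taken from the fit. It held no shift of a whole lineage or assay set, so these rates need not hold for the measured values.

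Before the data were examined, 29 gene lists of miRNA families, clusters, miRNAs with roles in colorectal cancer and markers of other cell types were fixed, as was the rule for the miRNAs named. The rule took, in each lineage, the 8 largest folds in each direction among miRNAs with a Ct under 32 in the brighter line, and the 3 largest bounds in each direction. Over both lineages it took up to 10 miRNAs in each shared direction and up to 5 in each order of opposite directions, ranked by the smaller fold. It also took miRNAs past the limma threshold, members of the lists as examples, and RNU44 and RNU48. Names follow the assay labels, in which # marks the minor arm of a hairpin. Because 10 names were borne by 2 assays, the assay number is given for such a name.

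The alternatives were median centring of each line, scaling to the mean of RNU44 and RNU48, quantile normalization, median centring within each assay set, Ct limits of 32 and 38, fold thresholds of 1.5 and 4, counting miRNAs detected in 1 line at their bound, the authors' deposited folds, limma without the block, limma with a mean-variance trend, and each line left out in turn. The deposited rounded ratios in place of the rebuilt values, and list percentiles after centring within each set, were added after seeing the data. Assays were matched to the RefSeq gene table of assembly GRCh38.p14 for neighbourhood alone. Of 754 assays, 625 matched 1 gene each, over 465 genes, and no coordinates are given because the files name no build. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.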

Results

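The study compared miRNA levels between colorectal cancer cell lines of low and high metastatic ability. Real-time PCR assays for 754 miRNAs were run on total RNA of KM12C and KM12SM (the KM12 lineage) and of SW480 and SW620 (the SW lineage). KM12C and SW480 formed the poorly metastatic group and KM12SM and SW620 the highly metastatic group, with 1 sample per line. A Ct was obtained for 346 miRNAs in KM12C, 331 in KM12SM, 369 in SW480 and 359 in SW620. At a Ct under 35 the numbers were 304, 285, 335 and 328, and 230 miRNAs were detected in all 4 lines. Across those 230 miRNAs, which are not independent replicates, the normalized profiles correlated most closely between SW480 and SW620 (Pearson r = 0.952). The KM12C and KM12SM profiles had r = 0.863, and pairs across lineages had values from 0.749 to 0.848.

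In the KM12 lineage, KM12SM had lower levels than KM12C of miR-455-3p (log2 fold -6.37), of miR-375 (-6.14), a miRNA of endocrine cells, and of miR-99b (-5.18). It also had lower levels of miR-135b (-4.42), which targets APC, of the epithelial miR-429 (-4.42), of miR-203 (-4.21), which represses p63 in skin, of miR-301 (-4.43) and of miR-30a-3p (-4.43). Higher in KM12SM were miR-449 (4.34), a relative of the p53-induced miR-34, miR-486 (3.71), a miRNA of red blood cells, miR-146a (3.54), a feedback inhibitor of NF-kappaB signalling, and miR-148a (3.37). They were followed by miR-596 (3.13), miR-320B (2.67), miR-875-5p (2.58) and miR-766 (2.46). Detected in KM12C alone were miR-224, miR-150 and the endothelial miR-126, with log2 bounds of at least 8.29, 8.23 and 7.98 in favour of KM12C. Detected in KM12SM alone were miR-10b# (at least 5.39), miR-500 in assay 001046 (at least 5.34) and miR-33a (at least 3.54), the last of which lies in the SREBF2 gene.

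Of 252 miRNAs detected in both KM12 lines, 140 were at least 2-fold lower and 29 at least 2-fold higher in KM12SM. A further 52 were detected in KM12C alone and 33 in KM12SM alone. The median log2 fold of all 252 miRNAs was -1.26, equal to 2.39-fold lower, on the authors' scale. That median became -0.13 with each line centred on its median, 0.30 with scaling to RNU44 and RNU48, 0.00 after quantile normalization and 0.16 with centring within each assay set. In the same order the numbers of higher and lower miRNAs became 67 and 65, 89 and 50, 69 and 61, and 60 and 49. All 29 higher miRNAs and 31 of the 140 lower miRNAs stayed at least 2-fold different under all 4 of these scalings. Each of these scalings raised the median fold above -1.26, which favours higher miRNAs and removes lower ones. The unequal shares are therefore no sign that the higher folds are the more reliable. Several of the higher miRNAs were close to the detection limit in KM12C, where the Ct was 34.89 for miR-449, 34.92 for miR-146a and 34.29 for miR-148a. Among the lower miRNAs, miR-455-3p and miR-30a-3p were close to that limit in KM12SM, at 34.94 and 34.49. The other lower miRNAs named above had a Ct of 32.97 or less there. A Ct limit of 32 left 10 higher and 100 lower miRNAs. No replicate check exists for these folds.

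The low median in KM12 lay mainly in 1 of the 2 assay sets. Among 136 set A miRNAs the median log2 fold was -1.77, with 105 at least 2-fold lower and 4 higher. Among 116 set B miRNAs, which hold many minor arms such as let-7b# and miR-22#, the median was -0.15, with 35 lower and 25 higher. The sets also differed in raw Ct without any normalizer, with medians of -1.22 in set A and 0.56 in set B. In the SW lineage the set medians were 0.00 over 185 miRNAs in set A and -0.43 over 114 miRNAs in set B.

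**Figure D1:**
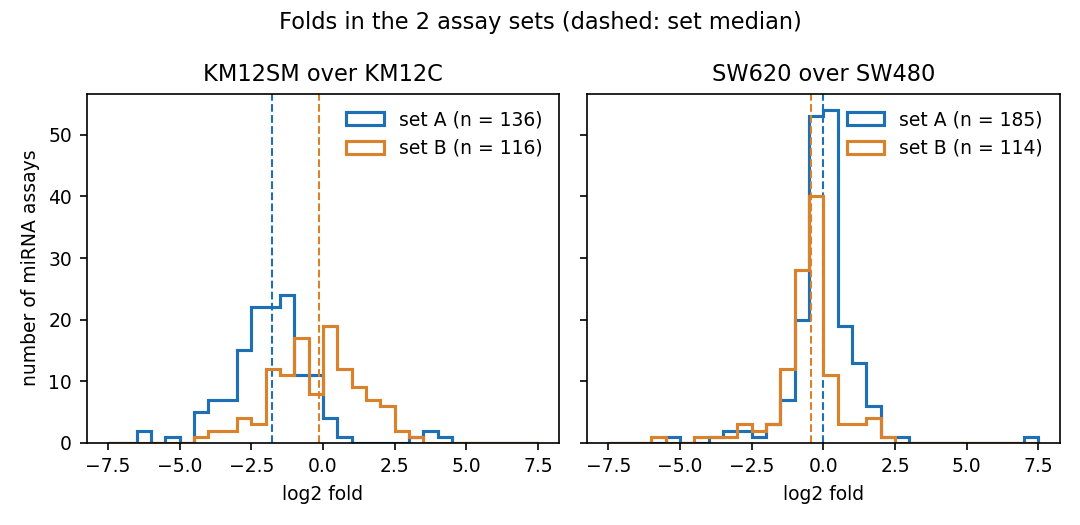
Histograms of the log2 fold of the highly over the poorly metastatic line for miRNAs of set A and set B in the KM12 lineage (left) and the SW lineage (right), with the number of assays per 0.5 log2 on the vertical axis and dashed lines at the set medians. The medians in KM12 were -1.77 for set A and -0.15 for set B, and those in SW were 0.00 and -0.43.

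Among the fixed families, the epithelial miR-200 family, repressors of ZEB1 and ZEB2, had the lowest KM12 percentile on the authors' scale. Its median log2 fold was -3.40, or -2.15 relative to the median of all miRNAs, at percentile 0.425 of random lists. The group of miR-99, miR-100 and miR-125 had a median of -3.47 over 4 miRNAs (percentile 1.56), with values of -5.18 for miR-99b, -4.06 for miR-125a-5p, -2.88 for miR-100 and -2.67 for miR-99a. Relative to all miRNAs it stood at -2.22, and at -3.35 over the 2 miRNAs left at a Ct limit of 32. All 12 detected members of the MYC-driven miR-17-92 cluster and its paralogs were at least 2-fold lower, with a median of -2.18 (percentile 1.69) and values of -2.82 for miR-19a and -2.50 for miR-18a. All 12 belonged to set A, and after centring within each set their median was -0.27, at percentile 10.3. After the same centring the miR-200 family stood at percentile 1.02 and the group of miR-99, miR-100 and miR-125 at 3.26. The pair of neuroendocrine miRNAs, miR-375 and the assay named dme-miR-7, had a median of -3.73, at percentile 1.54 and at 0.78 with centring within each set. Their log2 folds were -6.14 for miR-375 and -1.32 for dme-miR-7, the latter close to the median of all miRNAs (-1.26).

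The other families in KM12 stood between percentiles 5.92 and 91.1 and are given relative to the median of all miRNAs. All 7 members of the let-7 and miR-98 family, targets of LIN28, that were detected in both KM12 lines were at least 2-fold lower on the authors' scale, with log2 folds of -3.35 for let-7a and -3.88 for miR-98. The eighth, let-7c, was detected in KM12SM alone, at a Ct of 34.40 against 35.30 in KM12C. The median of the 7 relative to all miRNAs was -1.18. All 7 belonged to set A, and centring within each set moved this to -0.68 and the percentile from 5.92 to 26.7. It was -0.71 at a Ct limit of 38 with let-7c included and -0.72 at 32. Relative medians were -1.52 for the cluster of miR-221 and miR-222, which includes miR-221 at -3.98, and -1.48 for the HOX-embedded group of miR-10 and miR-196, which includes miR-10a at -3.56. The latter was -0.21 at a Ct limit of 38, where it held 4 miRNAs in place of 3. Colorectal cancer miRNAs had a relative median of -1.20, with log2 folds of -2.02 for miR-21, -2.88 for miR-31 and 0.90 for miR-155. Relative medians were -0.79 for the family of miR-15 and miR-16, -0.33 for the miR-29 family (0.17 with centring within each set, -0.58 after quantile normalization and -0.07 at a Ct limit of 32), -0.16 for the miR-30 family (0.48 at a Ct limit of 32, -0.03 after quantile normalization) and -0.01 for the clusters of miR-23, miR-27 and miR-24 (0.49 with that centring). With centring within each set the family of miR-15 and miR-16 stood at -0.29, the miR-30 family at -0.42, the colorectal cancer miRNAs at -0.70 and the HOX-embedded group at -0.98. The singly named miRNAs had a relative median of -0.60 (-1.15 at a Ct limit of 32) and included the hypoxia-induced miR-210 at -3.47. Above the median of all miRNAs were the group of miR-192, miR-194 and miR-215 at 0.59 (0.22 after quantile normalization and 1.09 with centring within each set), the 14q32 imprinted cluster at 0.61 (0.23 at a Ct limit of 38 and 1.11 with that centring), the striated muscle miRNAs at 0.89 and the blood miRNAs at 1.77. The last list joined miR-486 at 3.71 and miR-142-3p at -2.68, and its miR-150 was detected in KM12C alone. At a Ct limit of 38, with miR-150 as the third miRNA, its relative median was -1.39. The cluster of miR-183, miR-96 and miR-182 stood at 0.06 and turned to -0.03 with median centring, -0.03 with scaling to RNU44 and RNU48, and -0.26 after quantile normalization, and it was 0.56 with centring within each set and 0.45 at a Ct limit of 38.

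In the SW lineage, SW620 had lower levels than SW480 of miR-200b# (log2 fold -5.80), of miR-145 (-5.20), a miRNA of smooth muscle, and of miR-1243 (-4.39). The epithelial miR-141 and miR-200c had log2 folds of -3.73 and -3.26, and miR-374b#, mmu-miR-379 and let-7f-2# had -3.76, -3.29 and -3.08. The largest higher fold was that of miR-338-3p, which lies in an intron of the neuronal kinase gene AATK, at 7.08. It was followed by miR-548b (2.82), miR-361-3p (2.17), the muscle miRNA miR-133a (1.96), miR-21# (1.93), miR-181c (1.79), miR-346 (1.74) and the intestinal miR-215 (1.68). Detected in SW620 alone were miR-486-3p (at least 5.89), miR-615-5p (at least 4.24) and miR-505 (at least 3.30). Detected in SW480 alone were miR-875-5p, miR-571 and miR-143, with bounds of at least 4.99, 3.34 and 3.28 in favour of SW480. Of these, miR-143 is transcribed together with miR-145.

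Of 300 miRNAs detected in both SW lines, 41 were at least 2-fold lower and 30 at least 2-fold higher in SW620, and the median log2 fold was -0.14. A further 35 were detected in SW480 alone and 28 in SW620 alone. Scaling to RNU44 and RNU48 moved the median to -0.88 and gave 10 higher and 130 lower miRNAs. The numbers of higher and lower miRNAs were 39 and 36 with median centring, 41 and 29 after quantile normalization and 28 and 33 with centring within each set. Of the 30 higher miRNAs 10, and of the 41 lower miRNAs 23, stayed at least 2-fold different under all 4 scalings. With scaling to RNU44 and RNU48, 10 higher and 41 lower miRNAs stayed. The numbers were 30 and 36 with median centring, 30 and 26 after quantile normalization and 25 and 31 with centring within each set. Scaling to RNU44 and RNU48 lowered the median, which removes higher miRNAs. The unequal shares are therefore no sign that the lower folds are the more reliable. For miR-338-3p the authors' deposited table gave a fold of 134.93, while the assay of the other arm, miR-338-5P, had a Ct of 34.64 in SW480 and 34.97 in SW620. Several of the lower miRNAs were close to the detection limit in SW620. There the Ct was 34.98 for let-7f-2#, 34.59 for miR-200b#, 34.43 for miR-374b# and 34.21 for mmu-miR-379, against 30.97 for miR-141 and 25.16 for miR-200c. A Ct limit of 32 left 14 higher and 19 lower miRNAs. No replicate check exists for these folds.

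Among the families in SW, all 5 miR-200 members lay below the median of all miRNAs, and the family median of -1.15 was at percentile 0.325. The group of miR-99, miR-100 and miR-125 lay above it, with a median of 0.86 over 5 miRNAs at percentile 99.8, although its member miR-125b had a log2 fold of -1.18. The fibroblast and smooth muscle miRNAs, of which miR-145 and miR-199a-3p were detected in both lines, had a median of -3.08 at percentile 2.02. That median joined log2 folds of -5.20 for miR-145 and -0.96 for miR-199a-3p. Relative to the median of all miRNAs, the cluster of miR-424 and miR-503 stood at 1.30, with log2 folds of 1.19 for miR-424# and 1.16 for miR-450b-5p. The major arm miR-424 had -0.30, at a Ct of 34.00 in SW480 and 34.05 in SW620. The miR-181 family stood at 1.05, the miR-34 family at 0.82, the miR-29 family at 0.59, the blood miRNAs at 0.57 and the group of miR-192, miR-194 and miR-215 at 0.41. The miR-181 value joined log2 folds of 1.79 for miR-181c and 0.03 for miR-181a. The miR-34 value joined 1.96 for miR-34b in assay 002102 and -0.60 for miR-34a. The clusters of miR-23, miR-27 and miR-24 and the HOX-embedded group each stood at 0.30, colorectal cancer miRNAs at 0.21 and the family of miR-15 and miR-16 at 0.19. With centring within each set these 4 and the group of miR-192, miR-194 and miR-215 stayed above the median, at 0.015 to 0.235. Other settings raised 2 of them by more than 1.5 times, the colorectal cancer miRNAs to 0.60 at a Ct limit of 32 and to 0.33 with median centring or scaling to RNU44 and RNU48, and the family of miR-15 and miR-16 to 0.31 with the same 2 scalings. The group of miR-192, miR-194 and miR-215 stood at 0.18 at a Ct limit of 32. The cluster of miR-183, miR-96 and miR-182 stood at -0.58 (-0.30 after quantile normalization), with a log2 fold of -1.86 for miR-182. The C19MC placental cluster stood at -0.33 and turned to 0.52 after quantile normalization and to 0.35 at a Ct limit of 38, while it was -0.21 with median centring or scaling to RNU44 and RNU48 and -0.51 with centring within each set. The remaining lists lay within 0.14 of the median, on a side that changed with the scaling for all but the neuroendocrine miRNAs at 0.13. These were the miR-17-92 cluster at 0.13, the cluster of miR-221 and miR-222 at 0.14, let-7 at 0.11, the 14q32 cluster at 0.04 (-0.55 at a Ct limit of 38), the miR-30 family at 0.00 and the singly named miRNAs at -0.01, which include miR-885-5p with a log2 fold of -2.55. Over the other scalings and Ct limits these lists ranged from -0.55 to 0.28.

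Several lists had fewer than 2 miRNAs compared. In KM12 this was so for the miR-34 family, the miR-181 family, the cluster of miR-424 and miR-503, the C19MC cluster and the fibroblast miRNAs, and in SW for the striated muscle miRNAs. The pluripotency clusters, the X-linked miR-506-514 cluster, and the endothelial, neuronal and liver miRNAs had at most 1 miRNA compared in either lineage. The liver miRNA miR-122 had no Ct in any line. The small RNA RNU44 had a log2 fold of -2.18 in KM12 and 1.49 in SW on the authors' scale, and RNU48 had -0.67 and -0.22. Without a normalizer the Ct differences gave -1.58 and 1.62 for RNU44 and -0.24 and 0.11 for RNU48, so the direction of RNU48 in SW depended on the normalizer.

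Among 230 miRNAs detected in all 4 lines, 11 were at least 2-fold lower in both highly metastatic lines, where independent lists of these sizes would share 15.97. Ranked by the smaller fold, 10 of these were let-7f-2#, miR-200b#, miR-141, miR-1267, miR-203, miR-552, miR-429, miR-941, miR-200c and miR-31#. Higher in both were let-7b# (1.20 in KM12 and 1.35 in SW) and miR-22# (1.70 and 1.02), where 1.63 were expected from independent lists. With centring within each set the overlap lay above that of independent lists, with 5 lower (3.68 expected) and 5 higher (3.27 expected). The lower overlap was 2 with median centring (6.30 expected), 17 with scaling to RNU44 and RNU48 (21.3) and 3 after quantile normalization (4.87), and the higher overlap 6 (5.84), 3 (2.01) and 6 (6.30). Under all 4 other scalings, let-7f-2# (-3.64 and -3.08 on the authors' scale) and miR-200b# (-3.01 and -5.80) stayed at least 2-fold lower in both lineages. Near the detection limit were let-7f-2# in KM12SM and in SW620, at a Ct of 34.98 in each, and miR-200b# in SW620, at 34.59. In KM12SM the Ct of miR-200b# was 31.96. The KM12 values of miR-200c, miR-141, miR-552 and miR-1267 changed sign under at least 1 of those scalings. Across the 230 miRNAs, which are not independent replicates, the log2 folds of the lineages had a Pearson r of -0.12 and a Spearman rho of -0.18. With centring within each set these were 0.00 and -0.03, where the unrounded Pearson value was -0.0020.

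Opposite directions of at least 2-fold were seen for 15 miRNAs. Higher in KM12SM and lower in SW620 were 6, among them miR-596 (3.13 and -2.51), miR-1243 (1.70 and -4.39), miR-92a-1# (1.37 and -1.44), miR-1201 (1.35 and -1.32) and miR-939 (1.16 and -1.73). Lower in KM12SM and higher in SW620 were 9, among them miR-21# (-1.69 and 1.93), miR-361-3p (-1.61 and 2.17), miR-133a (-1.55 and 1.96), mmu-miR-124a (-2.49 and 1.53) and miR-331-5p (-1.31 and 1.42). Of the 15 miRNAs 4, namely miR-1243, miR-596, miR-92a-1# and miR-939, met the 2-fold rule in both lineages under all 4 other scalings. These numbers depended on the scaling, at 48 and 0 with scaling to RNU44 and RNU48, 10 and 9 with median centring, 9 and 9 after quantile normalization and 6 and 3 with centring within each set. The difference between lineages was not tested, since 1 line per label and lineage leaves no residual degrees of freedom.

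**Figure D2:**
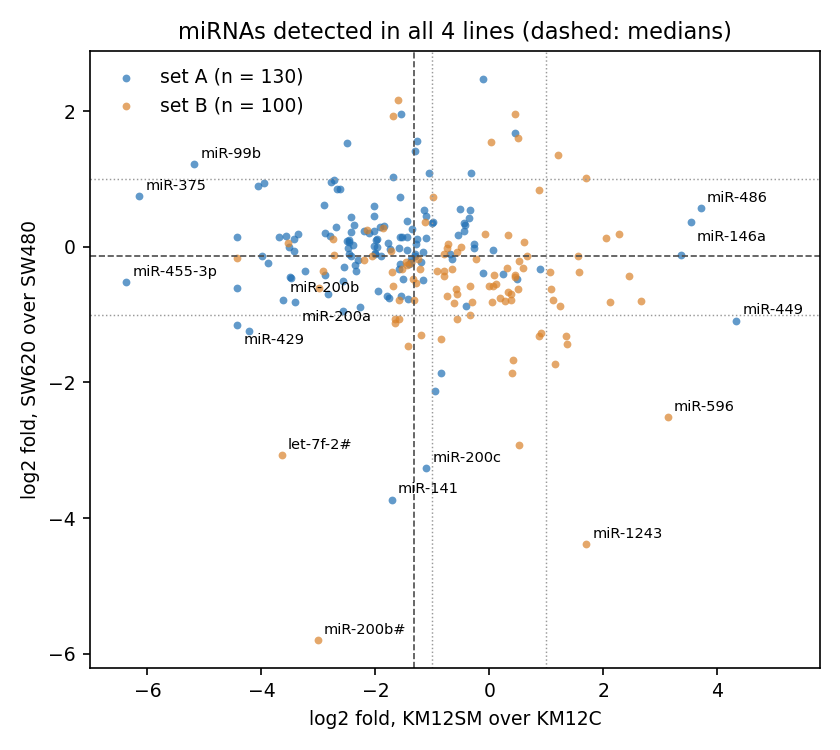
Scatter of 230 miRNAs detected in all 4 lines, with the log2 fold of KM12SM over KM12C on the horizontal axis and of SW620 over SW480 on the vertical axis, colored by assay set. Dotted lines mark 2-fold differences and dashed lines the medians. In the lower left, miR-200b# lies at -3.01 and -5.80 and let-7f-2# at -3.64 and -3.08, and most set A points lie to the left of set B.

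Over both lineages, the highly metastatic lines had lower miR-200b#, the minor arm of the miR-200b hairpin, than the poorly metastatic lines. Its log2 fold was -4.40 (SE 1.13, 95% confidence interval -6.64 to -2.17, adjusted p = 0.0307 in limma), and it was lower in 2 of 2 lineages. It was the only miRNA of 230 past the threshold, while 9 had an unadjusted p under 0.05 in limma, all lower. With no difference at all, more than 9 of 230 would be expected at that p. On the authors' scale the median of all compared miRNAs was -1.26 in KM12 and -0.14 in SW, which favours lower miRNAs. Those 9 included let-7f-2# (-3.36), miR-455-3p (-3.45), miR-429 (-2.79), miR-203 (-2.73) and miR-141 (-2.72), none of which passed the adjustment. Of these, miR-455-3p had -6.37 in KM12 and -0.52 in SW. The call on miR-200b# was lost under each other scaling, with adjusted p from 0.274 to 1.0, without the lineage block (0.883), with a mean-variance trend (0.106), at a Ct limit of 38 (0.143) and with any 1 line left out (0.184 to 0.992). Its log2 fold lay between -3.43 and -4.03 under those scalings, with an SE of 0.83 to 1.60, was -4.40 without the block, with the trend and at a Ct limit of 38, and ran from -3.52 to -5.29 with 1 line left out. At a Ct limit of 32 it was not compared. Under the other scalings the prior held 2.10 to 6.73 degrees of freedom and not the 1 common variance of the main fit, which raises p at a given SE. Fits with 1 line left out had no lineage block, so the origin entered this contrast. Without SW620, KM12SM alone stood against KM12C and SW480. The miRNAs called there, miR-142-3p, miR-375 and miR-100, also differed between origins and cannot be read as metastatic differences.

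The miR-200 family as a list was lower in the highly metastatic lines, with a median log2 fold of -2.20 over 5 members, or -1.46 relative to the median of all miRNAs. Camera gave an adjusted p of 6.42e-04, and over the other scalings and Ct limits adjusted p lay between 1.89e-06 and 0.0051. Those p-values take their spread over miRNAs and not over lines. The preset correlation of 0.01 treats the 5 members as nearly independent although they share hairpin clusters, so the p-values may be too small. Most scalings shift all 5 by the same constant per line, so the settings are not independent support. With an estimated correlation the p was 0.146 and the adjusted p = 0.970. Every list tested had that same adjusted p, because the adjustment gave all of them the largest unadjusted p. The call on the family was thus lost under this alternative. Its correlations came from 1 residual degree of freedom and ran from -1.0 to 1.0 between lists, with -0.20 for the miR-200 family. With so uncertain an estimate, this alternative decides nothing about the family. No member was called over all miRNAs, and 2 were called when adjusted over the list alone. In KM12 the log2 folds were -3.40 for miR-200a, -3.61 for miR-200b and -4.42 for miR-429, which share a hairpin cluster, and -1.11 for miR-200c and -1.71 for miR-141, which share another. In SW the order was the opposite, at -0.82, -0.79 and -1.15 against -3.26 and -3.73. The KM12 values of miR-200c and miR-141 changed sign under some scalings, up to 0.80 and 0.20 with centring within each set. None of the other 16 lists tested had an adjusted p under 0.05 in camera. The lowest among them was 0.424, for the blood and the neuroendocrine miRNAs, and no member of any of the 16 was called over all miRNAs. Adjusted over the list alone, 1 neuroendocrine miRNA was called and none in the other 15.

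**Figure D3:**
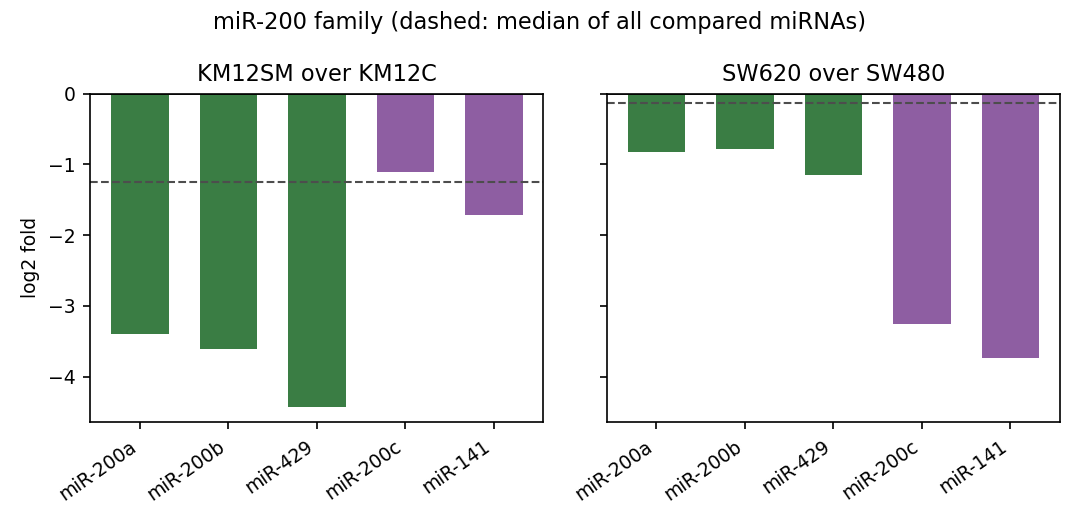
Bars of the log2 fold of the highly over the poorly metastatic line for the 5 miR-200 family members in the KM12 lineage (left) and the SW lineage (right), colored by hairpin cluster, with 1 sample per line and a dashed line at the median of all compared miRNAs. On the authors' scale the lower cluster mean was that of miR-200a, miR-200b and miR-429 in KM12 (-3.81) and of miR-200c and miR-141 in SW (-3.49). With other scalings the KM12 mean of miR-200c and miR-141 turned positive, up to 0.50.

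The comparison of origins holds 1 patient per origin, so the lines of an origin are not independent replicates and its p-values describe these 4 lines. SW lines had far more miR-142-3p, a miRNA of blood cells, than KM12 lines, with a log2 difference of 10.28 (limma SE 1.13, adjusted p = 1.22e-14). SW lines also had more miR-146a (6.96), miR-100 (6.83), miR-99a (6.15), miR-152 (4.81), miR-148a (4.25), miR-133a (4.09), miR-625 (3.96), miR-375 (3.88), miR-494 (3.75) and miR-27b (3.54). KM12 lines had more miR-155, miR-31, miR-31# and miR-203. In all, limma called 15 of 230 miRNAs, 11 higher and 4 lower in SW, and 41 had an unadjusted p under 0.05. Centring within each set gave 18 calls, 5 higher and 13 lower, and median centring gave 1. Scaling to RNU44 and RNU48 and quantile normalization gave 0 in limma, with 25 and 32 at an unadjusted p under 0.05. Without the metastatic label in the model limma called 7. It called 87 miRNAs without KM12C, 5 without KM12SM, 4 without SW480 and 3 without SW620, and miR-142-3p, miR-100 and miR-146a stayed past the threshold in all 4 of these fits. Each other called miRNA did so in 0 to 2 of the 4. The difference of miR-375 rested on KM12SM, without which it was 0.81 (6.95 without KM12C), and that of miR-494 was 1.91 without KM12SM. Both were past the threshold in 1 of 8 other settings. Without KM12C the difference was -1.36 for miR-203 (-3.46 in the full fit and -5.57 without KM12SM), -2.15 for miR-31 (-3.59 in the full fit) and 2.56 for miR-148a.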

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

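The tests on the miR-200 family were all chosen after the result was seen, and the tests of scaling were reworked after their values were seen. The tests on the assay sets were fixed before their results, but the reading of those on minor arms and on abundance was changed afterwards, to require a difference beyond its bootstrap spread. Each result below drew attention because the effect in KM12 and the effect in SW pointed in opposite directions. The differences between lineages, given as KM12 minus SW on the log2 scale, were not tested.

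The 2 assay sets moved apart in KM12, where the median of set B minus that of set A was 1.62, against -0.43 in SW, a difference of 2.04. Low abundance compressing the folds was argued against, since between a Ct of 28 and 32 the sets were still 1.32 apart (bootstrap 0.82 to 2.15). A higher fold of minor arms was argued against too, since within set B minor arms lay at -1.03 relative to the other assays (bootstrap -1.68 to -0.33), the opposite of what it needs. The bound written for that test was one of size, which was wrong because a difference of the other sign also excludes the explanation. Unequal reverse transcription or amplification of the sets in the KM12 lines stays open and may be the source. In 32 of 37 hairpins with an arm in each set the set B arm was higher, by a median of 1.20 (bootstrap 0.80 to 1.51). None of the 136 set A miRNAs was a # assay, so the minor arm of such a hairpin could lie in set B alone. The comparison of arms cannot by itself separate the set from the strand. A biological difference between the lines stays open as untested.

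Within the miR-200 family, the mean of miR-200a, miR-200b and miR-429 minus that of miR-200c and miR-141 was -2.40 in KM12 and 2.58 in SW, a difference of -4.98. All 5 belonged to set A, where scaling adds 1 constant per line, so the scaling was argued against as a cause of this difference, which was the same under 3 other scalings by construction and -2.32 and 2.30 after quantile normalization. For whether the members were lower at all, the scaling was argued against as the whole cause for miR-200a, miR-200b and miR-429 in KM12 and for miR-200c and miR-141 in SW, whose higher mean was still -1.90 under the least favourable of 4 other scalings. It may account for the low miR-200c and miR-141 in KM12, whose mean reached 0.50, and for miR-200a, miR-200b and miR-429 in SW it cannot be told apart from a change, since their mean of -0.66 had an SD of 0.20 around the bound of -0.5. Near-identical members read by each other's assays were not tested, and unequal change of the hairpin clusters cannot be told from their minor arms, since in SW miR-200a# and miR-200b# lay 5.19 apart and neither miR-200c# nor miR-141# had a Ct in SW620.

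Among single miRNAs higher in KM12SM and lower in SW620, the difference was 5.43 for miR-449, 5.64 for miR-596, 6.09 for miR-1243, 2.81 for miR-92a-1#, 2.67 for miR-1201 and 2.89 for miR-939. For miR-875-5p and miR-571, detected in SW480 alone in the SW lineage, the difference was at least 7.57 and 5.76. These directions held under all 4 other scalings wherever a fold was calculated, which for miR-875-5p and miR-571 was in KM12 alone. Their SW bounds were not recalculated.

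Among single miRNAs lower in KM12SM and higher in SW620, the difference was -6.40 for miR-99b, -3.62 for miR-21# and -4.02 for mmu-miR-124a, with both directions kept under all 4 other scalings. It was -3.78 for miR-361-3p and -3.51 for miR-133a, with both directions kept under 3 of the 4, and -2.73 for miR-331-5p, with both kept under 2. With a bound in 1 lineage it was -12.23 for miR-338-3p and -3.77 for miR-181c, each detected in KM12C alone in the KM12 lineage. It was -4.44 for miR-505, detected in SW620 alone in the SW lineage, whose KM12 direction held under 2 of the 4 scalings.

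The small RNA RNU44 differed by -3.68 on the authors' scale, at -2.18 in KM12 and 1.49 in SW, and its raw Ct values without a normalizer gave the same directions. The group of miR-99, miR-100 and miR-125 differed by -3.22 in its median relative to all miRNAs, at -2.22 in KM12 and 1.0 in SW, with both signs kept under all 4 other scalings.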

How the results depend on the processing

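Centring each line on its median gave 67 higher and 65 lower miRNAs in KM12, 6 higher and 2 lower in both lineages, and 1 call between origins. Scaling to RNU44 and RNU48 gave 89 and 50 in KM12, 10 and 130 in SW, 17 lower in both, and 0 calls between origins (25 at an unadjusted p under 0.05). Quantile normalization gave 69 and 61 in KM12, 6 higher and 3 lower in both, and 0 calls between origins (32 unadjusted). Centring within each assay set gave 60 and 49 in KM12 and 5 higher and 5 lower in both. A Ct limit of 32 gave 10 higher in KM12, 14 higher and 19 lower in SW, 0 higher in both, and 4 calls between origins. The 1.5-fold threshold gave 47 higher and 80 lower in SW and 31 lower in both. The 4-fold threshold gave 13 higher and 71 lower in KM12, 4 and 16 in SW, and 0 higher and 2 lower in both. Counting miRNAs seen in 1 line at their bound gave 46 higher in SW and 4 higher in both. The numbers in opposite directions, recounted under these alternatives after seeing the data (KM12 higher with SW lower, then the reverse), were 10 and 9 with median centring, 48 and 0 with scaling to RNU44 and RNU48, 6 and 3 with centring within each set, 3 and 5 at a Ct limit of 32, 11 and 15 at 38, 13 and 20 at 1.5-fold, 1 and 0 at 4-fold, and 11 and 21 with bounds counted.

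The Pearson correlation between lineages was -0.18 under each of median centring, the RNU44 and RNU48 scaling (-0.1771 both) and quantile normalization (-0.1768), -0.0020 with centring within each set, -0.25 at a Ct limit of 32 and -0.21 at 38. Spearman values were -0.26 under the first pair (-0.2634 both), -0.25 after quantile normalization, -0.0346 with centring within each set, -0.25 at 32 and -0.26 at 38.

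For highly against poorly metastatic lines, limma gave 0 calls under median centring (2 at an unadjusted p under 0.05), the RNU44 and RNU48 scaling (3), quantile normalization (2), centring within each set (11), a Ct limit of 32 (9) and a mean-variance trend (7), and 0 to 3 with 1 line left out. Without the lineage block limma gave 0 calls (4 unadjusted). Between origins it gave 7 without the metastatic label in the model, 9 with the trend and 3 to 87 with 1 line left out. The single call at a Ct limit of 38 was miR-126, lower in the highly metastatic lines, and not miR-200b#. The Ct of miR-126 was 27.57 in KM12C and 37.53 in KM12SM, a value admitted only by this looser limit. In SW the log2 fold of miR-126 on the authors' scale was 0.22, the other direction, so that call rested on the KM12 lineage alone. The miR-200 list kept its call under all 4 scalings and both Ct limits at the preset correlation. With an estimated correlation its adjusted p in camera was 0.970, as for every list tested, and the call was lost. That correlation came from 1 residual degree of freedom, so that setting cannot decide.

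Named KM12 folds turned positive for miR-361-3p (0.01), miR-200c (0.35), miR-505 (0.32), miR-1267 (0.19), miR-552 (0.43) and miR-331-5p (0.15) with scaling to RNU44 and RNU48, for miR-200c (0.62) and miR-552 (0.27) after quantile normalization, and for miR-133a (0.36), miR-141 (0.20), miR-200c (0.80), miR-505 (0.77) and miR-331-5p (0.60) with centring within each set. The scaling to RNU44 and RNU48 and the centring within each set add 1 constant per line or set, which gives these changes by construction. For quantile normalization the cause was not tested. No SW fold of at least 2-fold named here changed sign. The deposited rounded ratios, an alternative chosen after seeing the data, moved no count by more than 1.5 times. A Ct limit of 32 removed 45 of the 131 named folds, so that detection near the limit bounds what these values can show.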

Other observations

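The tests in this part were fixed before their results were seen, except that the reading of the test on failed wells was tightened afterwards. That reading required its exact interval to lie above 50%.

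Minor arms of hairpins added detail on the miR-200 family, and they were chosen after their values were seen. In KM12 the log2 folds were -2.99 for miR-200a#, -3.01 for miR-200b#, -2.00 for miR-200c# and, at a Ct of 35.18 in KM12SM and so above the limit, -2.03 for miR-141#. In SW the major arm miR-200b had -0.79 and miR-200a# had -0.61, while miR-200b# had -5.80, from a Ct of 28.79 in SW480 to 34.59 in SW620. The miR-200c# assay had a Ct of 37.79 in SW480 and miR-141# one of 34.31, and neither had a Ct in SW620. The single miRNA called between the metastatic groups thus had SW neighbours from the same hairpin cluster with far smaller folds.

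Some miRNAs were plainly present in 1 line of a lineage, with a Ct under 32, and above 35 or without a Ct in the other. There were 30 such cases, and 15 had a neighbour that could be measured, either the other arm of the hairpin or a miRNA gene within 10 kb. In KM12 both miR-224 and its neighbour miR-452 were seen in KM12C alone, as were both arms of the miR-126 hairpin, and miR-455-3p had a log2 fold of -6.37 where miR-455 was lost. In KM12SM alone, miR-33a was seen with a higher miR-33a# (2.14 above the median of all miRNAs), and miR-424# together with miR-503. The Ct of miR-33a# was 32.71 in KM12C and 31.12 in KM12SM, so it met the rule of 2 log2 only because that median was -1.26. In SW miR-143 was lost in SW620 where miR-145 had -5.20. In the other 7 cases the neighbour did not move that way, among them miR-338-3p in KM12 with its other arm at Ct 31.99 and 31.93, and miR-505 in SW. The neighbour moved the same way in 8 of 15 cases, 53.3% (exact 95% interval 26.6 to 78.7). The background was 289 other cases, in which an assay could count once per lineage. Their neighbour was lost or moved by at least 2 log2 in either direction in 24.9%, which is a wider measure. The written bound of 50% against single failed wells was met only with miR-33a# counted, and not beyond that interval. Failed wells therefore cannot be told apart from changes of the RNA for these assays as a group. The pairs miR-224 and miR-452, and the arms of miR-126, were counted from both sides. No biological explanation was tested.

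A hypothesis was that miRNA genes within 10 kb of each other would have similar folds, as parts of shared transcripts. In KM12, 44 such pairs within an assay set had a median absolute difference of 0.62 on the log2 scale, against 1.37 in random pairings of the same miRNAs, and their folds correlated with r = 0.58 across pairs, which are not independent. In SW, 67 pairs had 0.47 against 0.78 and r = 0.33. At most 0.2% of 10000 random pairings gave a difference as small in either lineage, which is consistent with shared transcription of neighbouring genes. Neighbours of similar sequence that are read by each other's assays could add to this, and that was not separated.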
